A study of Drosophila melanogaster with 8 samples.

How the data were processed

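RNA from Drosophila melanogaster embryo cells was sequenced in 8 libraries, made from 4 independent sorts. Per the labels' protocols, embryos carrying an EGFP reporter driven by the enhancer E10 were collected for 1 h, aged for about 11 h at 25 °C to early stage 14 and dissociated. EGFP-positive cells were sorted with a 488 nm laser in a gate set on wild type cells. From each sort the labels give 1 EGFP-positive sample, called GFP-positive here, and 1 sample of 50000 cells taken from the parent scatter gate, called all cells here. The all-cell samples therefore hold EGFP-positive cells too. The series' design text calls these background samples GFP-negative instead; the sample labels are followed here. For each sample 5 ng of total RNA was amplified after ERCC spike-in RNA was added, per the labels' protocols. The labels name Mix 2 of the spike-ins for all 8 samples.

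The authors deposited 1 table of genes and 1 of isoforms. Per the submitters' processing notes, the tools were TopHat 1.4.0, Cufflinks 1.3.0 and Cuffdiff 1.3.0 on build dm3; their parameters, the annotation release and the use of strand are not given in the sources used here. The deposited values are FPKM per the file headers, 1 column per library, whereas the tables' names say RPKM and the design fixed for this work assumed RPKM; the test for such values is the same. The authors also deposited a mean and an SD of the GFP-positive FPKM columns. Further deposited columns hold Cuffdiff log2 fold changes, q-values and calls, each for 1 GFP-positive library against the all-cell library of its sort. The gene table lists 15182 fly rows and 92 ERCC spike-ins, and 25406 fly isoforms are listed beside the same spike-ins. Of 37 mitochondrial rows, 34 were listed at 0 in all 8 libraries. No per-sample column was left unused. Coordinates are on dm3 and were converted from the tables' 0-based starts. A gene table on a later assembly, Release 6, was used only to match 17 members of the gene lists by name, and 3 members (Bc, tal and Mex1) were not matched.

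No read counts were used here, so depth was estimated from the low values. FPKM multiplied by locus length formed steps in short loci with 1 isoform, and the first step was taken as 1 fragment. By this estimate 1 fragment on a 1 kb transcript was worth 0.112 to 0.178 FPKM in the GFP-positive libraries and 0.0865 to 0.103 FPKM in the all-cell libraries. That corresponds to about 5610000 to 8910000 fragments and 9720000 to 11550000 fragments. A floor of 3 fragments on 1 kb lay at 0.337 to 0.535 FPKM and 0.26 to 0.309 FPKM, counting error only. The peak rule and its smoothing were settled after the steps had been seen.

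Fly genes with an FPKM of 1 or more in at least 4 of the 8 libraries were tested. The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1), GFP-positive minus all cells, two-sided, without a block. Fold changes on this scale understate the change of low genes. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Isoforms were tested in the same way. For ovo, ab and library measures an exact two-sided permutation test was used, whose smallest p for 4 against 4 libraries is 0.0286. The 27 gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation. The test and the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The genes named are the 12 with the largest rise and the 12 with the largest fall among called genes at 5 FPKM or more in 1 group that moved the same way in all 4 sorts. Added to these are ovo and ab and up to 4 called members per list, those with the largest change, or the 2 most abundant where none was called. For isoforms the rule names those of ovo and ab and the 3 largest in each direction. Other genes named were chosen after their values were seen, and the text says so. In simulated data with 10943 genes, 200 of them were changed. Of these, 28.5% were recovered for a change of 1 log2 unit and 83.5% for a change of 2, with 0 and 6 false calls. Far more genes, 5498, were called in the real comparison, so these rates do not carry over to it.

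The labels tie the libraries to numbered sorts, so that the numbers pair the samples. Deviations from the group means correlated between the libraries of a sort by 0.44, 0.10, 0.41 and 0.17 for sorts 1 to 4. The highest correlations with a library of another sort were 0.27, 0.04, 0.15 and -0.03. A fit with the sort as a replicate block was an alternative. Other alternatives were the pseudocount, the filter, quantile, upper quartile and TMM-like scaling, scaling by the ERCC sum, array weights, a test against a log2 fold change of 1, summed isoform values and leaving out libraries or sorts. Scaling by 1 ERCC subgroup, leaving out overlapping loci and keeping rows above 0 in all libraries were added after seeing the data. The subgroup to which each spike-in belongs is not given in the sources used here. It was written down from general knowledge of the product, after the spike-in ratios had been seen. Figures were drawn with matplotlib in Python.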

Results

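The data compare the transcriptome of cells in which the E10 enhancer was active with that of all cells of the same embryos. E10 is an enhancer of ovo, also called shavenbaby, whose product directs the formation of trichomes, the cuticle hairs of the larva. Each group had 4 libraries, 1 from each of 4 independent sorts. FPKM values summed to between 482441 and 561280 per library. At least 1 FPKM was reached by 9580 to 10763 fly genes in the GFP-positive libraries and by 10156 to 11443 in the all-cell libraries. Pearson's r of the log2 values over genes was 0.926 to 0.957 among GFP-positive libraries, 0.942 to 0.975 among all-cell libraries and 0.777 to 0.882 between the groups; genes are not independent replicates.

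The first comparison concerned ovo itself, the gene that E10 controls. ovo (CG6824, chromosome X, 4942330 to 4964962 on dm3) stood at 262 ± 43.6 FPKM (SD, n = 4) in GFP-positive cells and at 41.6 ± 11.9 FPKM (SD, n = 4) in all cells, 6.29-fold higher. Its log2 fold change was 2.65 (SE 0.20, limma adjusted p = 1.5e-05), and it was higher in GFP-positive cells in 4 of 4 sorts. The exact permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow. abrupt (ab, CG4807, chromosome 2L, 11210681 to 11261080), which encodes a BTB zinc finger transcription factor, stood at 282 ± 35.5 FPKM against 142 ± 21.7 FPKM (SD, n = 4 each). Its log2 fold change of 0.98 (SE 0.15, limma adjusted p = 3.1e-04) lay 1.45 above the median of all genes, but became -0.07 when libraries were scaled by the ERCC spike-ins of subgroup B. That scaling shifted sort 4 the most. The locus of ab overlaps those of CG32830, cmet and a snoRNA, so that their fragments are not fully separable.

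**Figure D1:**
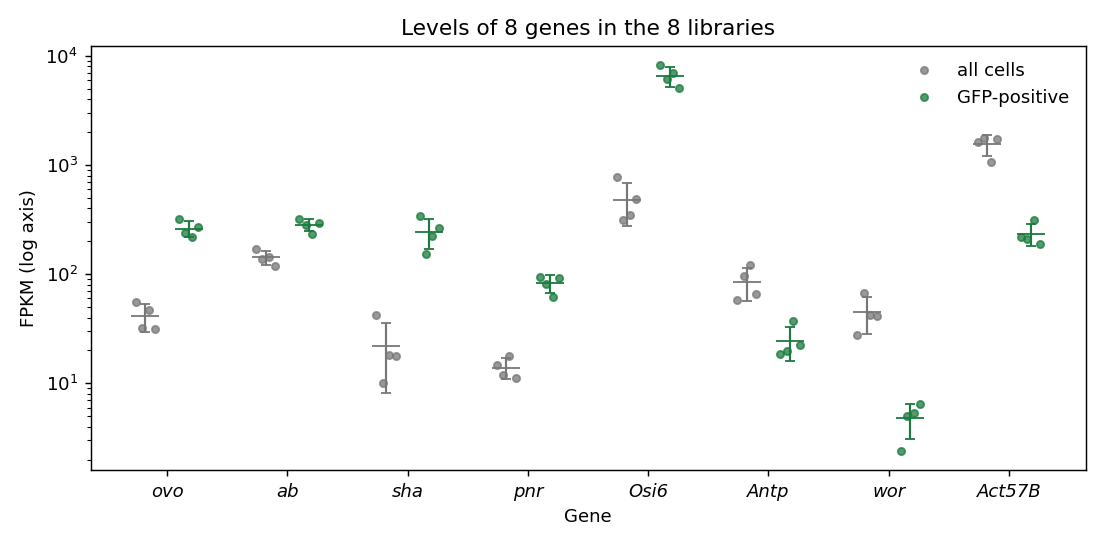
FPKM on a log axis of 8 genes in the 4 all-cell libraries (grey) and the 4 GFP-positive libraries (green); points are libraries, wide bars the means and error bars the SD. ovo, ab, sha, pnr and Osi6 were higher in each GFP-positive library than in any all-cell library, and Antp, wor and Act57B were lower; the rise of ab was lost when libraries were scaled by ERCC subgroup B.

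Across the genome, the genes with the largest rise in GFP-positive cells included genes of the cuticle and its pigment. They were CG12011, CG43332, Muc30E, CG15022, CG18088, CG7997, CG34224, TwdlD, y, tra, CG13705 and TwdlF, with log2 fold changes from 7.13 to 4.23. CG12011 reached 9077 ± 2685 FPKM against 93.6 ± 82.6 FPKM (SD, n = 4 each). yellow (y), needed for dark cuticle pigment, stood at 323 ± 71.6 FPKM against 16.1 ± 7.19 FPKM. The rank of CG12011 rested on all-cell library 4, where it stood at 12.5 FPKM against 52.2 to 203 FPKM in the other 3; without that library its log2 fold change was 6.38, below that of CG43332. TwdlD and TwdlF belong to the Tweedle family of cuticle proteins. The largest falls were those of Rfabg, a lipoprotein of the fat body, Obp99c, Argk, CG6415, CG31775, CG42586, CG3999, CG7227, Adh, CG5080, CG5177 and CG15828, with log2 fold changes from -4.34 to -3.36. Rfabg fell to 21.8 ± 18.1 FPKM from 394 ± 113 FPKM, and Argk, arginine kinase, to 79.4 ± 44.2 FPKM from 1038 ± 233 FPKM (SD, n = 4 each). GFP-positive library 3 raised the mean of Rfabg, at 48.8 FPKM against 10.7 to 14.4 FPKM in the others of its group. CG31775 and CG42586 had identical values in all libraries, so their fragments cannot be assigned to either copy. CG12011, CG7997, y, tra, Obp99c, CG6415 and Adh have loci that overlap another gene, and their values are uncertain to that extent.

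Of 10943 genes tested, limma called 1265 higher and 4233 lower in GFP-positive cells, and 318 and 379 of these differed at least 4-fold. In all 4 sorts 1209 of the genes called higher and 4141 of those called lower moved the same way. The split depended on the scaling: 23% of calls were higher as deposited, 52.8% with TMM-like scaling (2299 higher, 2058 lower), 45.0% with quantile normalization, 39.3% with upper quartile scaling and 4.66% with ERCC subgroup B (347 higher, 7096 lower). The median log2 fold change of all genes was -0.47 as deposited, -0.02 with TMM-like scaling and -1.35 with ERCC subgroup B, so that medians of gene lists are also given relative to all genes. All 1265 genes called higher and 2058 of those called lower were called the same way with TMM-like scaling, and 0 the opposite way.

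The gene lists of epidermal differentiation were higher in GFP-positive cells. Of 15 trichome effectors that act downstream of ovo, 13 rose and 0 fell, with a list median of 2.52, or 2.99 above all genes. The transmembrane zona pellucida proteins dyl and mey rose by 3.86 and 3.75 log2 units, and shavenoid (sha), needed for trichome growth, went from 22 ± 13.8 to 246 ± 77.4 FPKM (SD, n = 4 each). singed (sn, log2 fold change 0.01) and CG32397, the gene of jv (-0.31), did not pass the test; both were named after their values were seen. Of 23 cuticle and chitin genes 19 rose and 2 fell, among the former Tb, TwdlG and the chitin-binding Gasp, at 1474 ± 348 FPKM against 197 ± 95.6 FPKM (SD, n = 4 each). The Twdl and Cpr families of cuticle proteins had 32 rises and 4 falls among 83 genes, TwdlL among the rises at 3.55. GFP-positive library 4 was the lowest of its group in 24 of these 32 genes. TwdlL stood at 5.02 FPKM there and at 41.9 to 103 FPKM in the other 3, and Tb, of the cuticle and chitin list, at 3.82 against 27 to 60.6 FPKM. Both lay below all-cell library 1 (6.15 and 5.23 FPKM) but above the all-cell library of their own sort (1.22 and 1.04 FPKM). Without this library the log2 fold changes of TwdlL and Tb went from 3.55 to 4.44 and from 3.52 to 4.34. Of 19 Osiris genes, a cluster encoding putative transmembrane proteins, 17 rose and 0 fell, with Osi6 at 6561 ± 1344 FPKM against 482 ± 207 FPKM (SD, n = 4 each). Camera's adjusted p was 9.0e-14 for trichome effectors, 1.6e-12 for cuticle and chitin, 7.7e-12 for the Twdl and Cpr families and 6.2e-15 for the Osiris family. With an estimated correlation the adjusted p was 0.142, 0.192, 0.3 and 0.142. Scaled by ERCC subgroup B, 9 trichome effectors, 11 cuticle and chitin genes, 23 Twdl and Cpr genes and 13 Osiris genes were called higher and 2, 3, 11 and 0 lower.

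The lists of epithelial and dorsal genes had lower medians than those of epidermal differentiation, a difference that was not tested. Not all of their members rose, and the counts depended on the scaling. Of 28 genes of epithelial polarity and junctions 16 rose and 3 fell. The septate junction genes cora and sinu rose by 1.03 and 1.01 log2 units, and ed and sdt by 0.98 and 0.94. Under scaling by ERCC subgroup B these 4 stood slightly below 0, and sort 4 weighed most in this. Per fly FPKM, subgroup B was higher in GFP-positive than in all-cell libraries by 2.15 log2 units in sort 4. In sorts 1 to 3 it was higher by 0.69 to 0.97. Of 23 genes of the dorsal epidermis and dorsal patterning 11 rose and 1 fell. pannier (pnr), a GATA factor of the dorsal ectoderm, stood at 82.1 ± 15.2 FPKM against 13.9 ± 3.07 FPKM (SD, n = 4 each), scaf rose by 1.96, tup by 1.53 and Doc3 by 1.21. The list medians were 0.44 and 0.50, or 0.90 and 0.96 above all genes, with camera adjusted p = 9.2e-08 and 6.0e-06. With an estimated correlation the adjusted p was 0.142 and 0.126. With TMM-like scaling 22 epithelial and 14 dorsal genes rose and 0 of either list fell; scaled by ERCC subgroup B, which lowers all genes, 0 and 1 rose and 8 of each list fell. Of 19 genes of JNK signalling and dorsal closure 7 rose and 5 fell, with scaf and kay (1.10) among the rises, jar at 1.01, and bsk, which encodes JNK, lower by -1.10. With TMM-like scaling 13 rose and 1 fell, and with ERCC subgroup B 0 rose and 9 fell. Camera gave an adjusted p of 0.0143, and 0.363 as the adjusted p with an estimated correlation.

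Segment patterning genes, listed here as upstream of ovo, moved both ways, as did Hox genes and BTB transcription factors. Of 31 segment patterning genes 10 rose and 8 fell, against 15 and 2 with TMM-like scaling and 0 and 17 with ERCC subgroup B. wingless (wg), a secreted signal of segment patterning, went from 22.6 ± 3.74 to 67.7 ± 5.40 FPKM (SD, n = 4 each) and bowl rose by 1.3, whereas gsb (-1.61) and drm (-1.52) fell. The list median of -0.05 lay 0.42 above all genes while the mean was -0.01, and camera called the list higher (adjusted p = 0.0153, or an adjusted p of 0.498 with an estimated correlation). Of 12 Hox genes and cofactors 1 rose and 8 fell. Antp, Scr, Dfd and pb, which act in the head and thorax, had log2 fold changes of -1.74, -1.72, -1.66 and -1.75. abd-A, an abdominal Hox gene named after its value was seen, was the member that rose (0.46, limma adjusted p = 0.033). The Hox list was not called (camera adjusted p = 0.0873), and with TMM-like scaling 4 members fell and 1 rose, against 11 and 0 with ERCC subgroup B. Of 14 BTB transcription factors 4 rose, ken by 1.88 among them, and 7 fell, br (-2.43), CG16778 (-2.02) and bab2 (-1.56) among them. With TMM-like scaling 4 rose and 3 fell, and with ERCC subgroup B 0 rose and 9 fell. That list was not called (camera adjusted p = 0.855). Over all 10943 genes tested, 4233 were called lower and 1265 higher as deposited.

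Markers of the nervous system and of muscle were lower in GFP-positive cells. Of 20 neuronal markers 18 fell and 0 rose, fne (-2.78), VAChT (-2.65), scrt (-2.61) and onecut (-2.42) the most. Of 14 neuroblast markers 13 fell and 0 rose, wor going from 44.8 ± 16.5 to 4.80 ± 1.72 FPKM (SD, n = 4 each) and dpn, nerfin-1 and tap falling by 2.86, 2.68 and 2.66. Of 11 glial markers 8 fell, gcm, repo, gb and wrapper by 2.56 to 2.26, and 1 rose. Of 25 somatic muscle markers 20 fell and 0 rose, with Act57B at 233 ± 53.5 FPKM against 1543 ± 327 FPKM (SD, n = 4 each) and TpnC73F, sns and Mlc1 at -3.16, -3 and -2.36. Camera's adjusted p was 1.1e-04, 5.4e-04, 0.0369 and 7.9e-06 for these 4 lists. With an estimated correlation the adjusted p was 0.379, 0.313, 0.313 and 0.3. Relative to all genes the medians were -1.35, -1.68, -0.63 and -1.31. With TMM-like scaling 14, 10, 6 and 17 members fell and 0, 0, 1 and 2 rose.

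Several lists of markers of other tissues were not called, that of endoderm only narrowly. The endoderm median relative to all genes, -0.66, was close to the -0.63 of the glial list, which was called. Of 14 endoderm and gut markers 10 fell and 0 rose, Ptx1, nub, GATAe and fkh by 2.20 to 1.71; camera's adjusted p was 0.0531, and 0.0427 with the replicate block, but an adjusted p of 0.502 resulted with an estimated correlation. Of 9 fat body markers 6 fell, Rfabg, Adh, Lsd-1 (-3.21) and svp (-2.76) among them, and 1 rose (adjusted p = 0.0997, or 0.0407 with TMM-like scaling, and an adjusted p of 0.5003 with an estimated correlation). Of 14 hemocyte markers 4 fell, gcm, zfh1 (-2.06), nimC4 (-1.57) and srp (-0.99); the list median was 0.02, its mean -0.34 (0.735). Of 11 cardiac and visceral mesoderm markers 6 fell, Hand (-1.29) and mid (-1.17) among them, and 2 rose, tup among them (0.950). Of 11 salivary gland markers 3 fell, fkh and hkb (-1.66) among them, and 3 rose, eyg (1.16) and CrebA (1.12) among them (0.159). Of 9 germ cell markers vas (-2.64) and zpg (-1.76) fell and tud rose (0.64 as deposited, -0.41 with ERCC subgroup B; list 0.936). Of 13 sensory organ markers 6 fell, pros (-2.30), sc (-1.33) and neur (-1.03) among them, and 2 rose, Poxn (1.2) among them (0.660). Of 7 oenocyte markers svp and salr (-1.23) fell, and salm (0.71) and rho (0.50) rose as deposited, with salm at -0.33 and rho at -0.54 under ERCC subgroup B (list 0.187). Over all 10943 genes tested, 4233 were called lower and 1265 higher as deposited. A count of falls near that share is therefore no sign that a tissue was lost. These counts also depended on the scaling. With TMM-like scaling the rises and falls were 1 and 6 for endoderm, 1 and 4 for fat body, 3 and 3 for hemocyte, where srp lost its call (limma adjusted p = 0.124), 3 and 2 for cardiac and visceral mesoderm, where Hand lost its call (limma adjusted p = 0.248), 3 and 2 for salivary gland, 1 and 2 for germ cell, 2 and 3 for sensory organ and 3 and 2 for oenocyte markers. With ERCC subgroup B they were 0 and 12, 1 and 7, 0 and 7, 0 and 8, 0 and 5, 0 and 6, 0 and 10, and 0 and 3 in the same order. Values in parentheses without a gene are camera adjusted p-values.

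Markers of the trachea and of the amnioserosa, the extraembryonic tissue of the dorsal side, were higher. All 21 tracheal markers tested rose, with a median of 2.23, or 2.70 above all genes, and Osi6, Osi7, Osi15 and Osi9 by 3.83 to 3.56. Of these 21 genes, 13 also belong to the lists of Osiris, cuticle, trichome or segment patterning genes. Some of the other 8, bnl and uif among them, are active outside the trachea, so the list is not specific to it. Both were named after their values were seen. The transcription factor trachealess (trh), named after its value was seen, went from 23.4 ± 2.35 to 70.6 ± 6.51 FPKM (SD, n = 4 each). Of 10 amnioserosa markers 8 rose, C15 by 2.92 and tup and Doc3 as above, and Kr fell (-1.71). Of these 8 genes, 6 also belong to the dorsal list (tup, ush, peb, Doc1, Doc2 and Doc3), so this result is in large part the dorsal one again; those not named above were named after their values were seen. Camera's adjusted p was 9.0e-19 and 6.0e-06. With an estimated correlation the adjusted p was 0.142 for both. Scaled by ERCC subgroup B, 12 tracheal markers rose and 0 fell, and 1 amnioserosa marker rose and 1 fell.

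Cell cycle genes fell with 24 of 25 members and 0 rises, among them mus209 (PCNA), polo, geminin and Mcm7 by 2.73 to 2.39 log2 units (camera adjusted p = 1.4e-07, or an adjusted p of 0.3 with an estimated correlation). Of 88 ribosomal protein genes 41 fell and 0 rose as deposited, RpS19b (-1.85), RpL34a (-0.91), RpL24-like (-0.73) and RpL7-like (-0.71) the most, whereas with TMM-like scaling 11 rose and 1, RpS19b, fell. Their median of -0.36 lay 0.11 above that of all genes although camera called the list lower (adjusted p = 0.0155). The direction turned with TMM-like scaling (0.00282) and the adjusted p was 0.772 with an estimated correlation. Of 23 heat shock and dissociation stress genes 5 rose, Gadd45 (1.61), W (hid, 1.27) and stv (1.08) among them, and 1 fell, grim (-2.79). The list was not called (camera adjusted p = 0.159), but this depended on single libraries. Camera's adjusted p was 0.0147 without all-cell library 3 and 0.708 without all-cell library 4. In all-cell library 3 stv stood at 215 FPKM, against 47.6 to 92.1 FPKM in the others of its group. With TMM-like scaling 5 rose and 1 fell, and with ERCC subgroup B 0 rose and 15 fell.

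Camera called 10 lists higher and 6 lower of the 27, and 0 and 0 with an estimated correlation. The counts adjusted over the list alone were the same in 21 lists. In the other 6 the rises and falls adjusted over the list alone were 11 and 9 for segment patterning, 1 and 9 for Hox genes, 7 and 6 for JNK signalling, 0 and 11 for endoderm, 3 and 1 for stress, and 0 and 38 for ribosomal proteins. Other groupings of the 8 libraries also gave many list calls, up to 19. Those with the most calls kept all but 1 library of each group together, so they hold part of the real difference and do not measure chance. The number of lists called still carries little weight by itself, since it depended on the camera setting and was 0 with an estimated correlation. Those 0 calls cannot be put down to the size of the correlation alone. For the dorsal list the estimate was 0.020, near the preset 0.01, yet the adjusted p went from 6.0e-06 to 0.126. Why the estimated setting called no list was not tested, so its result does not show that the lists are unchanged.

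**Figure D2:**
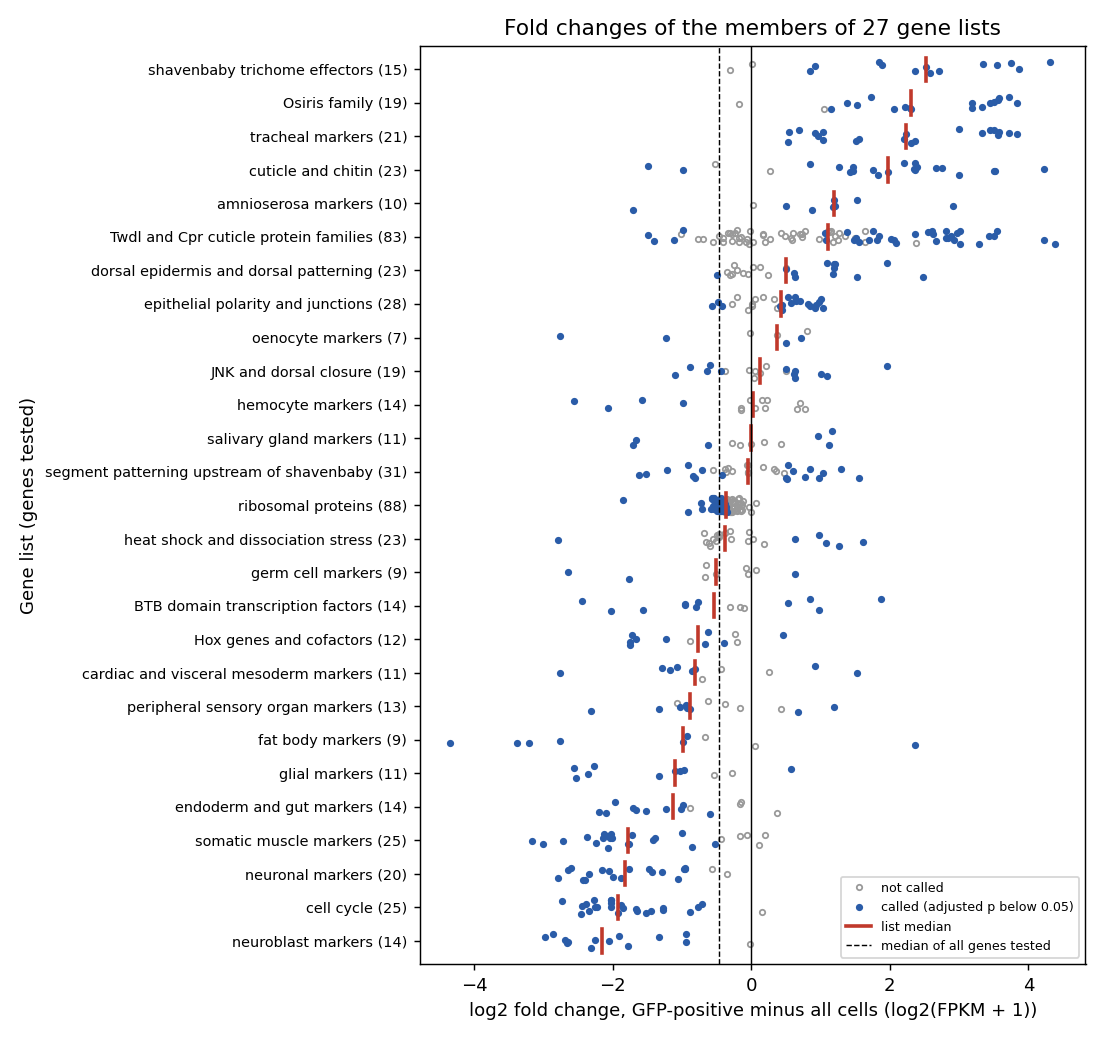
Log2 fold changes (GFP-positive minus all cells, log2(FPKM + 1)) of the tested members of 27 gene lists, sorted by list median; filled points were called at an adjusted p below 0.05, open points were not, red bars are list medians and the dashed line is the median of all genes, -0.47. Trichome effectors lie at the top with a median of 2.52 and neuroblast markers at the bottom with -2.15; as-deposited scaling is shown, and ribosomal proteins changed direction with TMM-like scaling.

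Isoforms were compared in the same way. ovo had 5 isoforms listed, of which ovo-RE passed the filter, at 261 ± 43.5 FPKM against 41.4 ± 11.9 FPKM (SD, n = 4 each; log2 fold change 2.66, limma adjusted p = 1.4e-04). All 4 isoforms of ab were tested. ab-RB rose from 85.4 ± 12.2 to 205 ± 38.3 FPKM (1.24) and ab-RA by 0.79 (limma adjusted p = 0.0439), while ab-RD (0.33) and ab-RC (-0.23) did not pass. CG12011-RA, CG43332-RA and Muc30E-RC rose most, and l(2)37Cc-RB (-4.76), Adh-RE (-4.70) and Rfabg-RA (-4.34) fell most. Of 16198 isoforms tested, 1503 were called higher and 4401 lower, and 2436 and 2141 with TMM-like scaling. Isoform values split fragments among overlapping transcripts and are less certain than gene values.

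In the authors' deposited table, Cuffdiff compared 1 library with 1 library in each sort and called 2229, 2201, 1704 and 1824 genes in sorts 1 to 4. According to the authors' deposited table, 674 tested genes were called in all 4 sorts, and limma called 671 of these here. Limma called 5498 genes in all, so most of its calls were not Cuffdiff calls in all 4 sorts. Cuffdiff called ovo, sdt, pnr and scaf in 4 of 4 sorts, bowl in 3, tup in 2, wg in 1, and ab, cora, sinu, ed and Doc3 in 0.

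The ERCC spike-ins took up 5.93% ± 1.12 of FPKM in GFP-positive libraries and 3.22% ± 1.52 in all-cell libraries (SD, n = 4 each), a difference of 2.71 percentage points (exact two-sided permutation test, p = 0.0286, the smallest possible). The single spike-ins did not move together, however. Of 92 spike-ins, 42 had at least 1 FPKM in all libraries. The mean log2 ratio of GFP-positive to all-cell FPKM had a median of -0.82 over the 12 of subgroup A, 1.13 over 8 of subgroup B, 1.69 over 10 of subgroup C and 2.24 over 12 of subgroup D. The means of single spike-ins did not overlap between subgroups. The sum over spike-ins is therefore not a measure of RNA content alone.

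**Figure D3:**
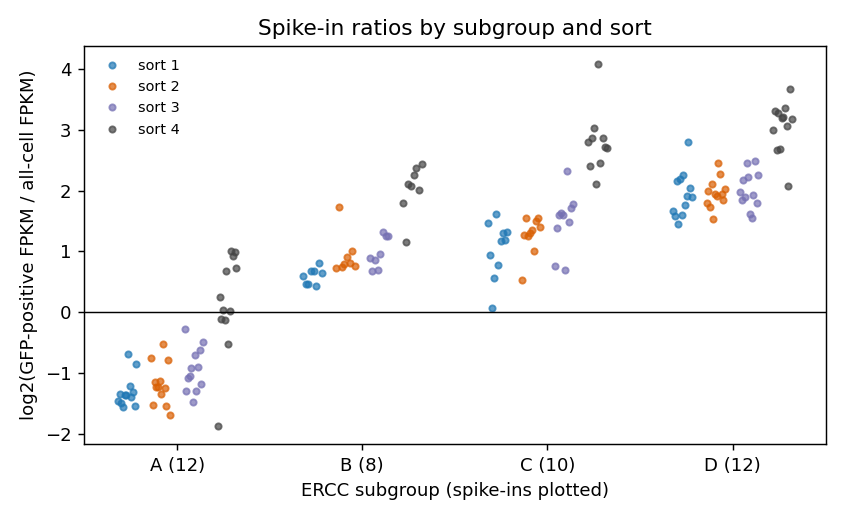
Log2 ratio of GFP-positive to all-cell FPKM of 42 ERCC spike-ins by subgroup (horizontal axis) and sort (colour); each point is 1 spike-in in 1 sort. Subgroup A lies lowest, with a median of -0.82, and subgroup D highest, with 2.24, and sort 4 lies above the other sorts in median in each subgroup.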

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

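The tests on spike-ins, on ribosomal protein genes and on tracheal markers were chosen only after the results were seen. The other tests were written down before their results, but the spread used for genes at 50 FPKM or more was changed afterwards.

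In 20 of 246 groups of 4 libraries, 1 library stood far from the other 3, where chance gives about 12.3. Library 3 of the GFP-positive cells stood above the others in 9 of them, with 48.8 FPKM for Rfabg, 8.71 for Obp99c, 4.55 for CG3999, 19.1 for Adh, 21.9 for CG5177, 9.15 for CG15828, 9.11 for Scr, 10.9 for gb and 103 for TpnC73F. Among the 379 genes at least 4-fold lower in GFP-positive cells, this library was the highest of the 4 in 57.8%. Over all 4233 lower genes it was the highest in 32.8% and library 4 in 35.6%, where chance gives 25%. GFP-positive library 4 stood above the others for CG18088 (145 FPKM), CG34224 (1140) and gsb (4.57), and below for CG31775 and CG42586 (0.311 each) and jar (69.5). GFP-positive library 1 stood above for zpg (1.53) and RpL34a (214). All-cell library 1 stood above for CG43332 (26.4), and all-cell libraries 4 and 3 below for bsk (74.8) and geminin (47.2).

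The spike-ins, whose subgroups the main comparison did not use, gave a signal of their own. Subgroup D exceeded subgroup A in the log2 ratio of GFP-positive to all-cell FPKM by 3.11 on average over the sorts, with 3.27, 3.18, 2.93 and 3.05 in sorts 1 to 4. The product has a pair of mixes whose subgroups differ in amount, and all-cell libraries with Mix 1 beside GFP-positive libraries with Mix 2 would give 3. Relative to subgroup B, subgroups A, C and D stood at -1.95, 0.56 and 1.11, where -2, 0.58 and 1 would follow from that. A bias of the amplification by length or abundance was argued against, since the difference was 3.06 (SE 0.05) after adjustment for both. A candidate explanation is that the groups received different mixes, although the labels name Mix 2 for all samples; no biological explanation was tested, and the subgroups were recalled after the ratios were seen.

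The median gene was lower in GFP-positive cells by -0.47 on the log2 scale. Whether loss of transcripts of other cell types alone lowered it cannot be told apart. Ribosomal protein genes, taken by name, served as genes that for the most part all cells use. Their median was -0.36, but its spread over the sorts was wide (mean -0.37, SD 0.17, n = 4). The bound of -0.2 set for this test lay within 2 SD. The 318 genes at least 4-fold higher held 16% ± 2.67 of fly FPKM in GFP-positive and 1.55% ± 0.58 in all-cell libraries (SD, n = 4 each), which alone predicts a shift of -0.23, just under 0.5 of the observed one. Genes at 50 FPKM or more had a median of -0.21 (mean over the sorts -0.2, SD 0.05, n = 4), at the same bound, so the part played by the lower estimated depth of the GFP-positive libraries cannot be told apart. For ribosomal protein genes and for genes at 50 FPKM or more, the spread over sorts replaced a bootstrap over genes after its outcome was seen. The narrower bootstrap interval for ribosomal protein genes had argued against the loss of other cell types. That for genes at 50 FPKM or more, -0.27 to -0.15, held the bound of -0.2. The larger share of ERCC subgroup B in GFP-positive libraries, which gives a median of -1.35 when used for scaling, stays unexplained.

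All 21 tracheal markers were higher in GFP-positive cells as deposited, and 12 with ERCC subgroup B scaling. Genes shared with the lists of cuticle, Osiris, trichome and segment patterning genes were argued against as the whole cause. The median of the 8 members outside these lists lay above that of all genes by 1.53 on average over the sorts (SD 0.38, n = 4). All 8 were called higher as deposited and with TMM-like scaling; with ERCC subgroup B, which lowers all genes, 1 was. Camera's adjusted p for the 8 was 1.5e-07, and an adjusted p of 0.142 resulted with an estimated correlation. The measure was settled after 2 earlier forms of the test, based on camera, had been seen; 1 argued against the explanation and 1 left it open. The median of trh, btl and dys lay 1.5 above that of all genes and each was called as deposited, which is consistent with tracheal cells in the sorted fraction; their levels in GFP-positive cells were 70.6, 10.3 and 12.3 FPKM. The 8 genes were trh, btl, dys, vvl, kni, knrl, uif and bnl, named after their values were seen. Their activity in epidermal cells was not tested and stays open. Some of them, vvl, uif and bnl among them, are active outside the trachea.

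Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called 5498 genes. The highest other split called 0. For isoforms the real split called 5904 and the highest other 3, again with 1 of 35 splits as large. Every other split mixes the groups, so the group difference enters its residual spread and few calls were likely in advance. The real split is also just 1 of the 8 that part all 4 sorts. These counts of genes and isoforms therefore cannot exclude chance. For gene lists 7 of the 35 splits called as many as the 16 of the real one, and the highest other called 19. The other splits with 16 or more kept all but 1 library of each group together, so they hold much of the real difference. Splits with equal shares of both groups on each side called at most 11. The splits therefore cannot decide whether chance gives as many list calls as the real one. Among the 8 splits that part all 4 sorts the highest others were 0 genes, 1 isoform and 19 lists.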

How the results depend on the processing

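The rise of ovo kept its direction and its call under all alternatives run, with log2 fold changes from 1.60 (ERCC subgroup B) to 3.20 (TMM-like scaling). Scaling by the spike-ins, by subgroup B (chosen after seeing the data) or by their sum, turned several genes: under subgroup B ab stood at -0.074, cora at -0.025, ed at -0.074, jar at -0.039, sdt at -0.10, sinu at -0.045, rho at -0.54, salm at -0.33 and tud at -0.41, and under the sum rho at -0.43, salm at -0.22 and tud at -0.30. The shift of all genes by these scalings is the cause. For subgroup B it rests most on sort 4. There subgroup B per fly FPKM was higher in the GFP-positive library by 2.15 log2 units, against 0.69 to 0.97 in sorts 1 to 3.

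Genes called higher and lower numbered 2063 and 2517 with quantile normalization, 2299 and 2058 with TMM-like scaling, 326 and 506 against a log2 fold change of 1, 347 and 7096 with ERCC subgroup B and 794 and 2413 without overlapping loci (fewer genes tested, 6399; chosen after seeing the data). The ERCC sum left 309 higher. Isoforms numbered 2261 and 2516 with quantile normalization and 2436 and 2141 with TMM-like scaling, and 2712 were lower with upper quartile scaling. With libraries or sorts left out, isoforms called higher ranged from 928 to 1425 and lower from 2259 to 4263, lowest without replicate 2.

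With an estimated correlation no list stayed called, so 0 were higher and 0 lower. The adjusted p was then 0.142 for amnioserosa, epithelial, Osiris, trichome and tracheal genes, 0.126 for dorsal epidermis, 0.192 for cuticle, 0.3004 for cell cycle, muscle and Twdl and Cpr genes, 0.313 for glial and neuroblast, 0.379 for neuronal, 0.363 for JNK, 0.498 for segment patterning and 0.772 for ribosomal genes. At the preset correlation the endoderm list passed with the replicate block (0.0427), pseudocount 5 (0.0479), quantile (0.028), upper quartile (0.0466) and TMM-like scaling (0.0333), array weights (0.0354) and subgroup B (0.019). The fat body list passed with quantile (0.0229), TMM-like (0.0407) and subgroup B scaling (8.4e-05), the Hox list without a filter (0.0494) and with quantile normalization (0.0353), and the stress list with array weights (0.00873). Lost were the glial list at 5 FPKM (0.117), the JNK list with quantile (0.0507) and subgroup B scaling (0.317), and the segment patterning (0.460) and ribosomal lists (0.131) with subgroup B. Ribosomal proteins turned with upper quartile (0.791) and TMM-like scaling (0.00282). With libraries or sorts left out, the adjusted p ranged from 0.0264 to 0.0926 for endoderm, 0.0447 to 0.151 for fat body, 0.0153 to 0.0609 for glial, 0.0147 to 0.708 for stress, 0.0443 to 0.202 for Hox, 0.00211 to 0.171 for ribosomal and 0.00302 to 0.0619 for segment patterning genes. The cause was not tested for these lists.

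The spike-in difference ranged from 2.09 to 3.14 percentage points with 1 library left out. The exact test lost its call without GFP-positive library 1, 2 or 4 or all-cell library 3 or 4 (p from 0.0571 to 0.114). Still, the groups overlapped in none of the 8 cases, and with 35 arrangements, 2 as extreme already end the call. With the spike-ins of subgroup B alone the difference was 0.595 percentage points. The replicate block gave 1442 genes higher and 4884 lower and changed the call of the endoderm list alone among lists and named genes. For the single genes and isoforms named, most comparisons with an alternative kept direction and call, and 113 lost the call, 44 of these against a log2 fold change of 1. Depth limits genes near the floor of 3 fragments, and a gene at 0 is listed at 0 rather than absent.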

Other observations

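Several groups of metabolic and housekeeping genes were looked at only after their values were seen, some of them because their members fell, so that their p-values restate that choice and cannot be read as tests. Of 13 enzymes of glycolysis and its branches 11 fell and 0 rose, with a median of -1.5 log2 units relative to all genes. Eno went from 149 to 14.4 FPKM, Pgm from 43.5 to 5.08, Pgk from 21 to 2.5, and ImpL3, lactate dehydrogenase, from 113 to 25.3 FPKM, whereas Hex-A (log2 fold change 0.09) and Pfk (-0.71) did not pass. Camera's adjusted p was 5.7e-04, and the adjusted p was 0.358 with an estimated correlation. With TMM-like scaling 10 fell and 1 rose. Somatic muscle markers, from a tissue rich in such enzymes, also fell (20 of 25, median -1.31 relative to all genes), and the part of muscle in the fall of these enzymes was not tested. The glycine cleavage genes ppl, CG6415 and CG3999 all fell, with log2 fold changes of -3.36, -3.67 and -3.63.

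Of 71 mitochondrial ribosomal protein genes 65 fell and 0 rose, and 54 fell with TMM-like scaling (relative median -1.10, camera adjusted p = 1.4e-10, adjusted p of 0.343 with an estimated correlation). Of 32 proteasome genes 25 fell as deposited and 10 with TMM-like scaling (0.00375, or 0.430 with an estimated correlation). Of 21 tRNA synthetase genes 9 fell and 2 rose (4 and 4 with TMM-like scaling; 0.286), and of 46 cytochrome P450 genes 7 fell and 6 rose (4 and 11 with TMM-like scaling; 0.0713); neither group was called.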
